A study of Ostreococcus tauri with 30 samples.

How the data were processed

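RNA was measured in 30 samples from liquid cultures of Ostreococcus tauri strain RCC745, a marine green picoalga. Per the labels' protocols, cells were grown in aerated flasks under a light-dark cycle of 12 h light and 12 h dark, in artificial seawater with Keller nutrients (0.88 mM nitrate and 22 µM phosphate). Copper was added at a lower or a higher final concentration, and cells were taken after 1, 4 and 12 h, with control samples at 0, 1, 4 and 12 h. The labels of the samples give the copper levels as 25 and 250 µM, whereas the treatment protocol and the names of the deposited comparison tables give 0.4 and 2 µM. Both pairs order the groups alike, so the levels are called lower and higher copper here and no dose in µM is attached to an effect. The labels do not state that replicates came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

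Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a stranded TruSeq kit for polyadenylated RNA, and single reads of 50 nt were sequenced on a HiSeq 2000. The deposited gene table holds read counts per gene, not normalized by the authors, for 7627 genes in 30 libraries. An extra line without a gene name, which held 0.00038% of all counts, was left out of library sizes and tests. A second deposited table holds counts per KEGG module in the same 30 libraries, which per the labels came from a homology search of the sequences against the KEGG database. KEGG modules are named sets of gene families with a shared pathway or complex. A family can belong to several modules, and the module counts of a library sum to about 10 times its gene counts, so module counts share reads with one another. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here. Overlapping genes, antisense genes and near-identical gene copies therefore carry an uncertainty that could not be assessed.

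The authors' 9 deposited comparison tables give, per the file headers, a log2 fold change with its standard error, a test score (the Wald statistic), an unadjusted p-value and an adjusted p-value for each gene. The submitters' processing notes name DESeq2 without a version, and the column names are those of that package. Judged from the mean levels beside them, the deposited log2 fold changes were shrunken toward 0. These tables were used only to count the authors' calls and to rank genes. The table for lower copper at 4 h names genes with a shorter prefix. Its numbers were matched to the current locus tags, because the fold changes then ranked with those fitted here (Spearman's rho across genes 0.985), which they did not through the older locus tags (0.108).

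Gene counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults for the 10 groups, which left 7190 genes and removed 437. Libraries were scaled by TMM, and the quasi-likelihood test was run on 1 fit of 10 group means over all 30 libraries with 20 residual degrees of freedom. Adjusted p is by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The 16 comparisons were copper against the control of the same time (6), higher against lower copper at each time (3), later controls against the control at 0 h (3), and the change of a copper effect between consecutive times (4 interaction contrasts). The standard error of a log2 fold change is the fold change divided by the square root of its F statistic. CPM values are edgeR's counts scaled to a common total by TMM library size, given as mean ± SD over 3 libraries. Module counts were tested by the same procedure without a filter (236 modules), and module levels are CPM of module counts. The test of module counts was added after the design was fixed.

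The design, the tests, the gene lists, the rule for named genes and the first group of alternatives below were set before the data were examined. That rule took, for each copper comparison, the genes with the largest rise and fall among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the 3 and 3 libraries. It allowed 10 genes with a functional description and 2 without one in each direction for copper comparisons. It allowed 5 in each direction for control times. Gene names were looked up in a table of RefSeq genes of O. tauri (assembly of strain RCC4221), in which 7626 identifiers matched, but only 2 of them carried a symbol other than the locus tag and none a description used here. At most 2 rises and 2 falls per comparison are therefore named, by locus tag. The build behind the counts is not given in the sources used here, so no coordinates are printed. Chromosome numbers are those in the locus tags.

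For the same reason the fixed gene lists could not be filled, and the planned camera tests of those lists were not run. In their place, KEGG modules were assigned by name to the fixed lists before any module value was seen. Lists for splicing, protein secretion and the endoplasmic reticulum, RNA polymerases, the respiratory chain, amino acid synthesis and nucleotide synthesis were added at that point. The lists for chaperones, histones, autophagy and ubiquitin conjugation, and the circadian clock have no module. Module names come from KEGG and some describe processes of animals or bacteria. They are printed as names of sets of homologous families, and the members behind each count are not listed in the files used here.

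Total gene counts ran from 2549094 to 5232257 per library (median 4104008.5), and total module counts from 27534827 to 62565779. The square root of the common dispersion was 19.3% for genes and 25.1% for modules. No library was identical to another, and the smallest chi-square per degree of freedom between replicates was 4.04, above the value of 1 that sampling alone gives. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so single genes were tested only through the model across genes. The procedure was tested on simulated data for the comparison of higher copper with control at 4 h, with 200 of 7190 genes changed. Among 7140 tested genes, edgeR recovered 22.4% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 3 false calls. DESeq2 recovered 25.4%, 61.2% and 90.9%, with 11 false calls. Of 236 modules with 40 changed, edgeR recovered 21.4%, 76.9% and 100% at these sizes, with 0 false calls. A change under 1.5-fold was thus mostly not detectable in these simulations with 3 libraries per group. Genes and modules were drawn independently of one another there, whereas deviations of real replicates were shared by many genes. Recovery and false calls in the real data may therefore differ.

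The first alternatives were, for genes, DESeq2 1.42.0 (Wald test), DESeq2 size factors in the edgeR fit, no filter on low counts, a replicate block, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were the same alternatives for modules, a fit with the labels of control replicate 3 at 1 h and at 4 h exchanged, a fit without these libraries, and a fit with a covariate. The covariate is each library's score along the first principal component of the deviations of libraries from their group means. For genes this component held 50.5% of the variance within groups. For modules the score was computed from the module counts instead. Before this covariate, the component of the deviations themselves was tried and dropped, since it is uncorrelated with the groups by construction. Calls of the lower and higher copper comparisons share their controls. Their overlap was set beside 20 simulated sets per time, in which all 9 libraries were drawn from 1 mean and refitted. Those sets shared no calls and so give no reference for the number shared. The fold changes were set beside 1000 draws of 3 unchanged groups built from resampled deviations within groups. A first version that kept the control libraries fixed was replaced. The 3 controls per time cannot be divided into parts of 2 or more. Figures were drawn with matplotlib 3.10.9.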

Results

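Polyadenylated RNA of O. tauri RCC745 was profiled in 10 groups of 3 libraries each: controls at 0, 1, 4 and 12 h, and cultures at 1, 4 and 12 h after a lower or a higher addition of copper. The series asks how the transcriptome of this alga responds to a copper challenge. Copper is a cofactor of photosynthetic and respiratory electron carriers and is toxic in excess. Gene counts per library ran from 2549094 (control 12 h, replicate 2) to 5232257 (higher copper 12 h, replicate 3), with a median of 4104008.5. On the first principal component, which held 40.2% of the variance, libraries of 1 group lay far apart (16.3% for the second). In the module table, the columns of control replicate 3 at 1 h and at 4 h were each nearer to the gene column of the other library than to their own. Their module counts were 6.055 and 20.05 times their gene counts, against 9.891 to 12.2 times in the other 28 libraries. The labels of 1 of the tables are therefore in doubt for this pair, and values for controls at 1 and 4 h are given with the labels as deposited. On a time axis with the other 1 h controls at 0 and the other 4 h controls at 1, their gene columns lay at 0.904 and 0.403. This points to the gene table, although 0.403 lies between the 2 times. If so, module results with exchanged labels do not apply, and gene results that use these controls as deposited are the ones in doubt.

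Without added copper, transcript levels moved with time alone. The module of photosystem I (M00163), which passes electrons to ferredoxin, rose by 0.45 ± 0.12 (log2, SE) from 0 to 4 h, to 6610 ± 448 CPM from 4830 ± 259 CPM (SD, n = 3; edgeR adjusted p = 0.023). At 12 h it stood at 0.43 ± 0.12 above 0 h (adjusted p = 0.023). Photorespiration (M00532), the salvage of the product that Rubisco makes with oxygen, rose by 0.43 ± 0.099 at 4 h and 0.59 ± 0.099 at 12 h (adjusted p = 0.014 and 0.00051). The origin recognition complex (M00284), which marks replication origins, fell by 0.61 ± 0.14 and 0.69 ± 0.14 (adjusted p = 0.014 and 0.0023). The FtsH protease module (M00742), which includes thylakoid proteases in algae, fell by 0.37 ± 0.10 and 0.59 ± 0.10 (adjusted p = 0.04 and 0.00055). Glutathione synthesis (M00118) fell by 0.65 ± 0.18 at 12 h (adjusted p = 0.023). Synthesis of beta-carotene (M00097) rose by 0.36 ± 0.10 at both times (adjusted p = 0.04 and 0.031). The 4 h calls depended on the doubted controls. With both left out 1 of the 12 modules called at 4 h was called, serine synthesis (M00020), which fell, and none of those named here. With their labels exchanged 6 were called, of which 16.7% rose, and photorespiration and beta-carotene synthesis were not among them. With only the groups compared, these 2 were not called at 4 h, and photosystem I and beta-carotene synthesis not at 12 h. Photosystem I at 12 h was also lost with both doubted controls left out, and beta-carotene synthesis at 4 h with DESeq2 size factors.

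In these controls edgeR called 1 gene at 1 h (OT_ostta08g02060, which fell by 1.03 ± 0.17, adjusted p = 0.016). It called 4 genes that rose and 13 that fell at 4 h, and 161 that rose and 133 that fell at 12 h. Of modules, 1 fell at 1 h (the RPA complex, M00288, which binds single-stranded DNA, fell by 0.39 ± 0.084, adjusted p = 0.021). At 4 h 7 rose and 5 fell, and 10 rose and 10 fell at 12 h. At 12 h OT_ostta08g04240 rose from 6.73 ± 2.43 to 36.9 ± 10.5 CPM (log2 2.44 ± 0.46, adjusted p = 0.0043) and OT_ostta07g04760 rose by 2.00 ± 0.56 (adjusted p = 0.042). OT_ostta04g02890 fell by 3.02 ± 0.63 (adjusted p = 0.0099), from 3.81 ± 1.73 to 0.441 ± 0.162 CPM, and OT_ostta17g02020 fell by 1.89 ± 0.50 (adjusted p = 0.034). At 4 h OT_ostta11g00690 rose by 0.82 ± 0.15 (adjusted p = 0.018) and OT_ostta17g02080 fell by 1.13 ± 0.19 (adjusted p = 0.016). These counts moved with single libraries. At 12 h falls outnumbered rises without any control at 0 h, replicates 1 or 2 of control 4 h, control 12 h replicate 3, replicates 1 or 3 of lower copper 1 h, higher copper 1 h replicate 2, or replicates 1 or 3 of higher copper 4 h. At 12 h 42 genes were called without control 0 h replicate 3, 47 without control 12 h replicate 3, 137 without control 0 h replicate 1, 140 to 184 without control 0 h replicate 2 and control 12 h replicates 2 and 1, and 480, 481 and 512 without higher copper 1 h replicate 1 and lower copper 12 h replicates 3 and 1. At 4 h 0 genes were called without control 0 h replicates 1 or 2 by edgeR (722 at an unadjusted p under 0.05 with all libraries). The count was 1 without control 0 h replicate 3, 4 without control 4 h replicates 1 or 3, 10 without control 4 h replicate 2 and 44 without lower copper 12 h replicate 1. The 1 gene of 1 h was lost without control 1 h replicates 2 or 3 or control 0 h replicate 3. From 3 to 14 were called without replicate 1 of control 1 h, control 4 h, control 12 h, lower copper 1 h, lower copper 12 h and higher copper 1 h, replicate 2 of lower copper 1 h and higher copper 12 h, and replicate 3 of control 4 h and lower copper 12 h. The 12 h modules numbered 7, 9, 10 and 13 without control 0 h replicate 3, control 12 h replicates 3 and 2, and control 0 h replicate 2. The 4 h modules numbered 1 without control 0 h replicates 1 or 3 or control 4 h replicate 3. They numbered 5 without control 1 h replicate 1, control 4 h replicate 2 or lower copper 4 h replicate 2, 6 without lower copper 4 h replicate 1 or higher copper 1 h replicate 3. They numbered 7 without replicate 2 of control 0 h, control 12 h and lower copper 1 h or control 12 h replicate 3. At 1 h RPA was not called without control 0 h replicates 1 or 2 or control 1 h replicates 1 or 3, with the doubted labels exchanged, or with both doubted controls left out. OT_ostta07g04760 was not called with the component between replicates as a covariate. Without higher copper 1 h replicate 3, 3 modules were called, and 5 without control 12 h replicates 1 or 3, lower copper 12 h replicates 1 or 3, or higher copper 1 h replicate 1. With the doubted controls left out, 0 genes were called at 1 h (486 at an unadjusted p under 0.05), 6 at 4 h and 315 at 12 h. DESeq2 called 108, 144 and 585 genes with all libraries. The 108 included 0 of the genes called by edgeR at 1 h, so OT_ostta08g02060 was not called by DESeq2 there. Scaled by DESeq2 size factors, 2 genes rose and 13 fell at 4 h, and 4 modules rose and 6 fell.

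At 1 h after the higher addition, photorespiration (M00532) was already above the control. It rose by 0.53 ± 0.099 (log2, SE), to 28600 ± 4210 CPM from 19900 ± 1510 CPM (SD, n = 3; edgeR adjusted p = 0.0045). Synthesis of tyrosine (M00025), of methionine (M00017) and of isoleucine (M00570) rose by 0.46 ± 0.10, 0.38 ± 0.08 and 0.42 ± 0.12 (adjusted p = 0.014, 0.011 and 0.045). The glyoxylate cycle (M00012), which makes organic acids from acetyl-CoA, fell by 2.24 ± 0.59 (adjusted p = 0.03), at a low level of 4.02 ± 1.41 against 19 ± 5.57 CPM. Acylglycerol degradation (M00098), the release of fatty acids from storage lipids, fell by 1.18 ± 0.30 (adjusted p = 0.026). Of 5 splicing modules, the Prp19 complex (M00353) rose by 0.41 ± 0.11, the tri-snRNP (M00354) fell by 0.28 ± 0.08, and 3 did not pass (adjusted p = 0.037 and 0.045; 1 rose and 1 fell adjusted over the list alone). Of 12 amino acid synthesis modules methionine and isoleucine rose and 10 did not pass (2 adjusted over the list alone); tyrosine synthesis was assigned to no list.

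In all, 30 genes rose and 80 fell at 1 h, of which 16 and 5 changed at least 2-fold, and 7 modules rose and 5 fell. OT_ostta01g06030, on chromosome 1 by its locus tag, rose by 2.90 ± 0.61 to 4.6 ± 2.55 CPM from 0.561 ± 0.2 CPM (adjusted p = 0.016), and OT_ostta18g00970 rose by 2.38 ± 0.47 (adjusted p = 0.012). OT_ostta03g04260 fell by 1.48 ± 0.36 and OT_ostta05g03160 by 1.15 ± 0.21 (adjusted p = 0.04 and 0.01). No gene and no module was called by edgeR without control 1 h replicate 1, control 1 h replicate 2 or higher copper 1 h replicate 2, or when only the groups compared were fitted (709 genes and 26 modules at an unadjusted p under 0.05). DESeq2 called 213 genes and 15 modules. The gene count was 36, 64 and 66 without higher copper 1 h replicate 3, control 4 h replicate 2 and control 0 h replicate 2. The module count was 6 without lower copper 1 h replicate 2, control 1 h replicate 3 or higher copper 1 h replicate 3. It was 7 without replicates 2 or 3 of control 12 h, replicates 2 or 3 of lower copper 4 h, or lower copper 1 h replicate 3. With the doubted labels exchanged, 205 genes and 1 module were called, and OT_ostta01g06030 and the modules named here other than tyrosine synthesis were lost. With both left out, methionine synthesis, acylglycerol degradation and Prp19 were lost, and the tri-snRNP with DESeq2 size factors.

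At 4 h after the higher addition, photorespiration rose by 0.69 ± 0.099, a 1.61-fold difference, from 27400 ± 2670 to 44000 ± 2310 CPM (n = 3; edgeR adjusted p = 9.7e-05). Isoleucine synthesis rose by 0.70 ± 0.12 and tyrosine synthesis by 0.52 ± 0.10 (adjusted p = 0.00059 and 0.0014). The acyl-CoA synthesis step of beta-oxidation (M00086) rose by 0.73 ± 0.14 (adjusted p = 0.0012). Glutathione synthesis (M00118), which supplies the thiol peptide from which metal-binding phytochelatins are made, fell by 0.75 ± 0.18, from 1170 ± 139 to 699 ± 4.04 CPM (adjusted p = 0.0051). Synthesis of tocopherol (M00112), a lipid antioxidant, fell by 0.49 ± 0.14 (adjusted p = 0.023). Synthesis of pantothenate (M00119), a precursor of coenzyme A, fell by 0.78 ± 0.17 (adjusted p = 0.0034). The GINS complex (M00286), a part of the replicative helicase, fell by 0.60 ± 0.19 (adjusted p = 0.047). Tocopherol synthesis was not called without higher copper 4 h replicates 1 or 3 or control 4 h replicate 3, and GINS not without any of 14 libraries, these 3 among them. Both were lost with both doubted controls left out.

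By list, 2 of 12 amino acid synthesis modules rose (methionine and isoleucine), 1 fell (serine, M00020, which fell by 0.39 ± 0.075, adjusted p = 0.0012) and 9 did not pass (2 and 2 adjusted over the list alone). Of 10 modules of DNA replication and the cell cycle, GINS fell and 9 did not pass (1 rose and 1 fell adjusted over the list alone). Of 5 splicing modules the tri-snRNP fell by 0.32 ± 0.08 (adjusted p = 0.0073) and 4 did not pass (1 and 2 adjusted over the list alone). Both modules of photosystems and light harvesting lay below the control, at log2 −1.50 and −0.10, and neither passed (1 fell adjusted over the list alone). The only module of metal transport (M00240) lay at 0.38 and did not pass, although it did adjusted over the list alone. Of 7 modules of the respiratory chain 0 were called by edgeR, with log2 values from −1.99 to 0.20 (3 fell adjusted over the list alone). In all, 8 modules rose and 12 fell, and no single library changed this count by more than 1.5 times (14 to 27).

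At this time 287 genes rose and 374 fell, 123 and 71 of them at least 2-fold. OT_ostta01g06040 rose 13.3-fold (log2 3.74 ± 0.47, adjusted p = 1.8e-05), from 1.92 ± 0.225 to 25.9 ± 14.2 CPM, and is the neighbour by locus tag of OT_ostta01g06030. OT_ostta05g03500 rose 12.7-fold (3.66 ± 0.52, adjusted p = 5e-05), from 12.2 ± 1.89 to 155 ± 73.7 CPM. OT_ostta13g00885 fell by 2.14 ± 0.35 and OT_ostta11g02150 by 2.12 ± 0.59 (adjusted p = 0.00025 and 0.021). The number of genes was 380 without higher copper 4 h replicate 3 (203 rose and 177 fell, so the excess of falls turned), 404 without control 4 h replicate 1, 410 without higher copper 4 h replicate 1 and 435 without control 4 h replicate 3. DESeq2 called 803 genes, of which 655 were among the 661, and a fit of only the groups compared called 1028.

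**Figure D1:**
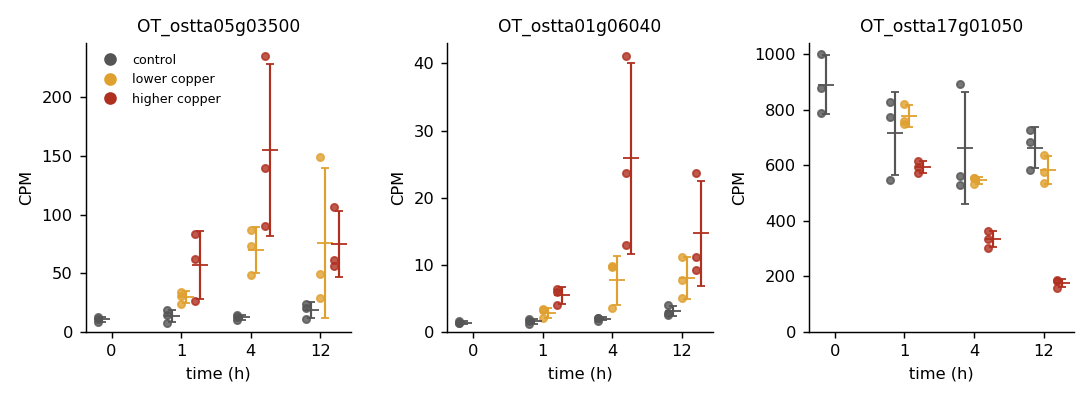
Levels of OT_ostta05g03500, OT_ostta01g06040 and OT_ostta17g01050 in CPM (vertical axes) against time after the addition in h (horizontal axes), with a point for each of 3 libraries per group and bars for mean ± SD. OT_ostta01g06040 reached 25.9 ± 14.2 CPM under higher copper at 4 h against 1.92 ± 0.225 in the control, and OT_ostta17g01050 stood at 176 ± 15 CPM under higher copper at 12 h against 664 ± 74.2.

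At 12 h after the higher addition, modules of the cell cycle and of checkpoints stood above the control, most of them called only with higher copper 12 h replicate 3 included. The G1/S transition (M00692), the set of regulators that commit a cell to DNA replication, rose by 0.91 ± 0.12, from 781 to 1470 CPM (means, n = 3; edgeR adjusted p = 1.3e-05). DNA damage-induced checkpoints (M00691) rose by 1.14 ± 0.19, from 1250 ± 113 to 2760 ± 504 CPM (adjusted p = 0.00044). RPA (M00288) rose by 0.39 ± 0.084, the leading-strand polymerase epsilon (M00263) by 0.59 ± 0.15 and APC/C (M00389), a ubiquitin ligase of mitosis, by 0.33 ± 0.10 (adjusted p = 0.0034, 0.011 and 0.027). GINS fell by 0.75 ± 0.19 (adjusted p = 0.011). Without that library, G1/S and the checkpoints were called, and RPA, polymerase epsilon, APC/C and GINS were not. APC/C was also lost without control 12 h replicates 1 or 3, and GINS without control 12 h replicate 3. With only the groups compared RPA and APC/C were not called. Of the 10 modules of DNA replication and the cell cycle, 4 rose, 1 fell and 5 did not pass (5 and 1 adjusted over the list alone). Of 4 modules of DNA repair 1 rose and 3 did not pass (2 rose adjusted over the list alone).

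Photorespiration rose by 0.46 ± 0.099 at 12 h (adjusted p = 0.0034). Glutathione synthesis fell by 0.63 ± 0.18 to 705 ± 103 CPM from 1090 ± 62.4 CPM (adjusted p = 0.016) and tocopherol synthesis by 0.52 ± 0.14 (adjusted p = 0.012). Of 5 splicing modules, Prp19 rose by 0.49 ± 0.11, the U1-snRNP (M00351) fell by 0.81 ± 0.19, the tri-snRNP fell by 0.31 ± 0.08, and 2 did not pass (adjusted p = 0.0056, 0.0063 and 0.011; 1 and 3 adjusted over the list alone). Of 5 modules of protein secretion 2 rose and 3 did not pass (2 adjusted over the list alone). The translocon-associated protein complex (M00402) rose by 0.89 ± 0.29 and N-glycosylation (M00072) by 0.24 ± 0.077 (adjusted p = 0.042 and 0.035). Histidine synthesis (M00026) fell by 0.34 ± 0.10 (adjusted p = 0.025), and the other 11 amino acid modules did not pass (1 fell adjusted over the list alone). Without higher copper 12 h replicate 3, photorespiration and Prp19 were called, and the other modules of this paragraph were not. Without control 12 h replicate 3 only the U1-snRNP was called beside photorespiration and Prp19. Glutathione synthesis was also lost without control 12 h replicate 2, N-glycosylation without control 12 h replicate 1, and histidine synthesis without replicate 2 of control 12 h or higher copper 12 h. The translocon-associated complex was also lost without replicate 2 of control 0 h, control 12 h or higher copper 12 h, or lower copper 1 h replicate 3, and with both doubted controls left out. With only the groups compared the tri-snRNP, N-glycosylation and histidine synthesis were not called. The single modules of the Calvin cycle and of the tricarboxylic acid cycle lay at 0.46 and 0.21, passing only adjusted over the list alone.

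Under higher copper, edgeR called no module at any of the 3 times from the lists of photosynthetic electron carriers, chloroplast ATP synthase, tetrapyrrole synthesis, carotenoid synthesis, proteasome, ribosomal proteins, nitrogen assimilation, sulfur assimilation, fatty acid synthesis, RNA polymerases and nucleotide synthesis. The 2 nitrogen assimilation modules lay at log2 1.54 and 1.71 at 1 h and at −0.31 and −0.17 at 12 h. The 3 RNA polymerase modules lay between −0.45 and −0.01 at 12 h, and the 2 ribosomal modules at −0.28 and −0.07. Adjusted over the list alone, the chloroplast ATP synthase (0.15) passed at 1 h.

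**Figure D2:**
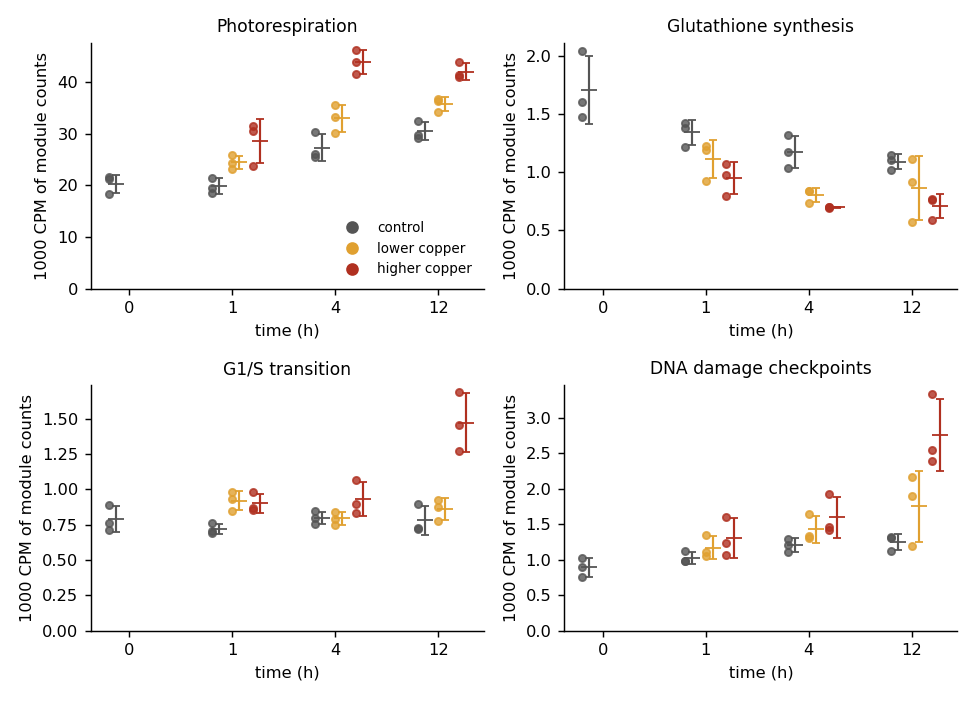
Levels of 4 KEGG modules (photorespiration, glutathione synthesis, G1/S transition and DNA damage checkpoints) in CPM of module counts, in units of 1000 CPM (vertical axes) against time in h (horizontal axes), with a point per library and bars for mean ± SD of 3 libraries. Under higher copper the G1/S module stood at a mean of 1470 CPM at 12 h, against 781 ± 102 CPM in the control and 860 ± 76.1 CPM under lower copper.

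At 12 h 350 genes rose and 502 fell, 154 and 102 of them at least 2-fold, and 21 modules rose and 18 fell. OT_ostta17g00300 rose by 3.83 ± 0.63 and OT_ostta04g02890 by 3.79 ± 0.60 (adjusted p = 0.00033 and 0.00024), to 9.95 ± 5.52 and 6.49 ± 1.2 CPM. Both 12 h controls lay near the floor, at 0.74 ± 0.751 and 0.441 ± 0.162 CPM. The fall of OT_ostta04g02890 in the control, from 3.81 ± 1.73 CPM at 0 h, rests on the same 12 h controls. OT_ostta17g01050 fell by 1.91 ± 0.17, from 664 ± 74.2 to 176 ± 15 CPM (adjusted p = 2.3e-07), and OT_ostta04g01940 fell by 1.88 ± 0.31 (adjusted p = 0.00034). Of the 293 tested genes on chromosome 19 and on the part of chromosome 2 up to OT_ostta02g02710, 1 rose and 105 fell (35.8% fell), against 349 and 397 of the 6897 other genes (5.76% fell). The edge on chromosome 2 was placed after the data were seen. It lies where the loadings of the main component within groups, in the order of the locus tags, divide best into 2 parts (31.8% of their variance). The level of these genes also varied between replicates of most groups, along that component. Without higher copper 12 h replicate 3, control 12 h replicate 3 or higher copper 12 h replicate 2, the counts were 297, 329 and 403 genes and 8, 14 and 24 modules. The excess of falls among genes was then absent: 159 rose and 138 fell, 172 and 157, and 224 and 179. With only the groups compared, 53.8% of the called genes rose, against 41.1%.

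**Figure D3:**
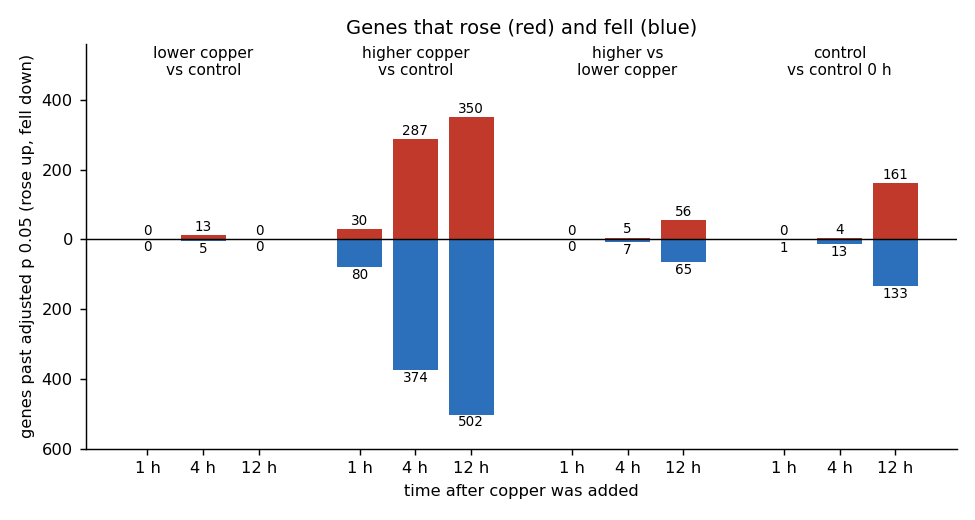
Number of genes (vertical axis) called by edgeR as risen (bars above 0) or fallen (bars below 0) for each comparison of copper with control and of higher with lower copper, by time (horizontal axis). Under higher copper the calls numbered 30 and 80 at 1 h, 287 and 374 at 4 h, and 350 and 502 at 12 h.

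Across times, 1222 genes were called at 1 or more times under higher copper, and 18 rose and 32 fell at all 3. Between 1 and 4 h, 26 genes rose at both and 71 fell at both, where independent lists would share 1.2 and 4.16. Between 4 and 12 h the numbers were 128 and 174 (14 and 26.1 for independent lists), and between 1 and 12 h 18 and 34 (1.46 and 5.59). No gene was called in opposite directions at 2 times. Of the 852 genes at 12 h, 43 were also called in the control between 0 and 12 h, 15 of them in the same direction. Both comparisons use the 12 h controls with opposite sign, which alone favours opposite directions. The directions therefore do not show that copper opposes the change with time.

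The test of the change itself called 1 gene between 1 and 4 h, OT_ostta03g02950 (chosen after its values were seen), and 0 genes between 4 and 12 h by edgeR (557 at an unadjusted p under 0.05; DESeq2 called 14). For modules edgeR called 0 in both (4 and 15 at an unadjusted p under 0.05), and DESeq2 called 0 and 1. The 1 gene was lost without control 1 h replicates 2 or 3, any control at 4 h, higher copper 1 h replicates 2 or 3, or higher copper 4 h replicate 1. Between 4 and 12 h, 1 gene was called without higher copper 4 h replicate 2 or 12 h replicate 3, 2 without control 0 h replicate 1 or control 1 h replicate 3, and 4 without control 4 h replicate 3. For modules 1 was called without higher copper 12 h replicate 1, control 12 h replicate 2 or higher copper 4 h replicate 3. A gene or module called at 1 time only is therefore not shown to respond differently over time. For lower copper edgeR called 0 genes and 0 modules in both tests (95 and 292 genes, and 6 and 4 modules, at an unadjusted p under 0.05), as did DESeq2.

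After the lower addition, changes passed the test mainly at 4 h, where 13 genes rose and 5 fell by edgeR. OT_ostta05g03500 rose by 2.51 ± 0.51, a 5.7-fold difference, from 12.2 ± 1.89 to 69.6 ± 19.3 CPM (n = 3; adjusted p = 0.039). OT_ostta02g05450 rose by 2.33 ± 0.42 (adjusted p = 0.023), from 5.95 ± 0.918 to 30.3 ± 10.7 CPM. OT_ostta05g03160 fell by 0.95 ± 0.21 and OT_ostta07g02490 by 0.93 ± 0.20 (adjusted p = 0.046 for both), the former not called with DESeq2 size factors. These genes lay at 3.66, 3.41, −1.51 and −1.60 under higher copper at the same time, all with an adjusted p of 5e-05 or lower.

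Of the 18 calls 72.2% rose, against 53.9% of those by DESeq2, 51.5% with only the groups compared and 44.3% with the component between replicates as a covariate. The lower copper calls at 4 h depended on the doubted controls: edgeR called 0 genes with their labels exchanged and 0 with both left out (602 and 737 at an unadjusted p under 0.05, against 943). DESeq2 called 102 with the labels as deposited and a fit of only the groups compared 204. Leaving out 1 library gave 0 calls without any control at 4 h or lower copper 4 h replicate 2. It gave 1 without lower copper 4 h replicate 3, 5 without lower copper 1 h replicate 2, 9 without lower copper 4 h replicate 1 and 10 without control 0 h replicate 1. It gave 11 without higher copper 12 h replicate 1, control 0 h replicate 2 or lower copper 12 h replicate 2. The counts were 44, 46, 53 and 64 without higher copper 1 h replicate 1, control 1 h replicate 3, and lower copper 12 h replicates 3 and 1.

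At 1 and 12 h after the lower addition edgeR called 0 genes (266 and 339 at an unadjusted p under 0.05), and DESeq2 called 0 and 10. For modules edgeR called 0 at 1 and 4 h (20 and 16 at an unadjusted p under 0.05; DESeq2 called 1 and 0). At 12 h DNA polymerase alpha with primase (M00261), which starts new DNA strands, rose by 0.47 ± 0.10, from 1530 ± 92.5 to 2110 ± 219 CPM (adjusted p = 0.026). Of the 10 modules of its list 1 rose and 9 did not pass (2 rose adjusted over the list alone). The call was absent with the doubted labels exchanged, with only the groups compared, and without replicates 1 or 2 of lower copper 4 h, replicates 1 or 2 of lower copper 12 h, lower copper 1 h replicate 2, replicates 2 or 3 of control 12 h, or control 4 h replicate 3. In turn, 5 modules were called without lower copper 12 h replicate 3. Glutathione synthesis lay at −0.55 at 4 h and did not pass over all modules.

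Higher and lower copper were also compared directly, at the same times. At 4 h photorespiration stood higher under higher copper, at 44000 ± 2310 against 33000 ± 2670 CPM (log2 0.41 ± 0.099, edgeR adjusted p = 0.04, n = 3), as did a dicarboxylic acid cycle module (M00171; 0.41 ± 0.097, adjusted p = 0.04). At 12 h the G1/S transition was 1.71-fold higher (0.77 ± 0.12, adjusted p = 0.00019). The module that KEGG names Wnt signaling (M00677), a set of kinase and ubiquitin ligase families in organisms without that pathway, was lower at −0.72 ± 0.17 (adjusted p = 0.038). The 4 h modules were not called with the doubted labels exchanged, with both doubted controls left out, or without any of 21 libraries. The exceptions, with counts of 2 to 7, were replicate 2 of control 4 h, control 12 h and higher copper 1 h, replicate 3 of lower copper 4 h, lower copper 12 h, higher copper 1 h and higher copper 12 h, and replicate 1 of lower copper 12 h and higher copper 1 h. The Wnt module was not called without replicate 1 of control 4 h, control 12 h, lower copper 1 h, lower copper 12 h and higher copper 4 h, replicate 2 of control 0 h, control 1 h, control 4 h, lower copper 12 h and higher copper 12 h, or higher copper 12 h replicate 3, and not with both doubted controls left out. At 12 h 9, 10 and 15 modules were called without higher copper 1 h replicates 3 and 1 and lower copper 12 h replicate 3. The G1/S module was called without each of the 30. Fitting only the groups compared, edgeR called 0 modules at either time (52 and 17 at an unadjusted p under 0.05), and DESeq2 called 13 and 14.

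Between the copper levels edgeR called 0 genes at 1 h (325 at an unadjusted p under 0.05; DESeq2 called 0), 5 higher and 7 lower at 4 h, and 56 higher and 65 lower at 12 h. Genes named by the rule at 12 h were OT_ostta06g02290 (2.79 ± 0.53, adjusted p = 0.0034), OT_ostta10g01450 (2.04 ± 0.52, adjusted p = 0.037), OT_ostta04g01940 (−1.83 ± 0.31, adjusted p = 0.00098) and OT_ostta12g02150 (−1.82 ± 0.22, adjusted p = 1.3e-05). At 4 h OT_ostta07g00240 and OT_ostta18g01100 were higher by 1.56 ± 0.31 and 1.52 ± 0.27 (adjusted p = 0.035 and 0.013). OT_ostta20g00035 was lower, at 256 ± 10.6 against 443 ± 23.5 CPM (−0.79 ± 0.14, adjusted p = 0.013), as was OT_ostta08g01870 (−1.09 ± 0.23, adjusted p = 0.049), which was lost with DESeq2 size factors, without a filter and with both doubted controls left out. At 12 h rises outnumbered falls without replicate 1 of control 12 h, lower copper 4 h, lower copper 12 h and higher copper 4 h, or replicate 2 of control 12 h, lower copper 1 h, lower copper 4 h and higher copper 12 h. The 12 h count was 661 without lower copper 12 h replicate 3, 211 without higher copper 1 h replicate 1. It was 72, 61, 67 and 68 without lower copper 12 h replicates 1 and 2 and higher copper 12 h replicates 2 and 3. The 4 h count stayed between 8 and 17 without replicate 1 of control 1 h, replicate 2 of control 0 h, control 1 h, lower copper 1 h and higher copper 4 h, or any replicate 3 other than those of control 0 h, lower copper 4 h and higher copper 4 h. Without lower copper 4 h replicate 3, lower copper 12 h replicate 1 and higher copper 1 h replicate 1 it was 63, 56 and 30. Without each of the other 15 libraries it was between 0 and 7. A fit of only the groups compared called 0 genes at both times (1461 and 520 at an unadjusted p under 0.05), and DESeq2 called 129 and 278.

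Both copper levels were set against the same 3 controls, which alone gives a correlation of their fold changes. At 4 h all 18 genes called under lower copper were called in the same direction under higher copper (13 rose and 5 fell). Across the 7190 genes, which are not independent replicates, Pearson's r of the fold changes was 0.599, 0.538 and 0.595 at 1, 4 and 12 h. For simulated unchanged groups the mean r was 0.467, 0.462 and 0.478. The simulated bounds were −0.26 to 0.894, −0.258 to 0.881 and −0.237 to 0.883, and each value of r lay inside them. The covariance was 0.0543, 0.102 and 0.0944. Simulated means were 0.0498, 0.0503 and 0.0517 (upper simulated bounds 0.202, 0.197 and 0.199). The differences were 0.00455, 0.0515 and 0.0427. All 3 covariances lay below the upper simulated bounds.

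In the authors' deposited tables, lower copper had 6, 368 and 0 genes with an adjusted p under 0.05 at 1, 4 and 12 h, higher copper 78, 970 and 874, and higher against lower copper 0, 248 and 32. Of these, 43, 577 and 605 genes were called in the same direction here for higher copper against control, as were 18 for lower copper at 4 h, and 11 and 32 for the levels compared at 4 and 12 h. Spearman's rho across genes between the deposited log2 fold changes and those fitted here was between 0.948 and 0.994 in the 9 comparisons. With the doubted control labels exchanged it was lower in the 4 comparisons that use these controls, from 0.846 to 0.928, against 0.963 to 0.993 with the labels as deposited. If the deposited values were computed from the same counts and labels, such a drop follows whichever labels are right. It therefore does not decide between them. The largest deposited rise, 2.67, was at 4 h under higher copper.

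**Figure D4:**
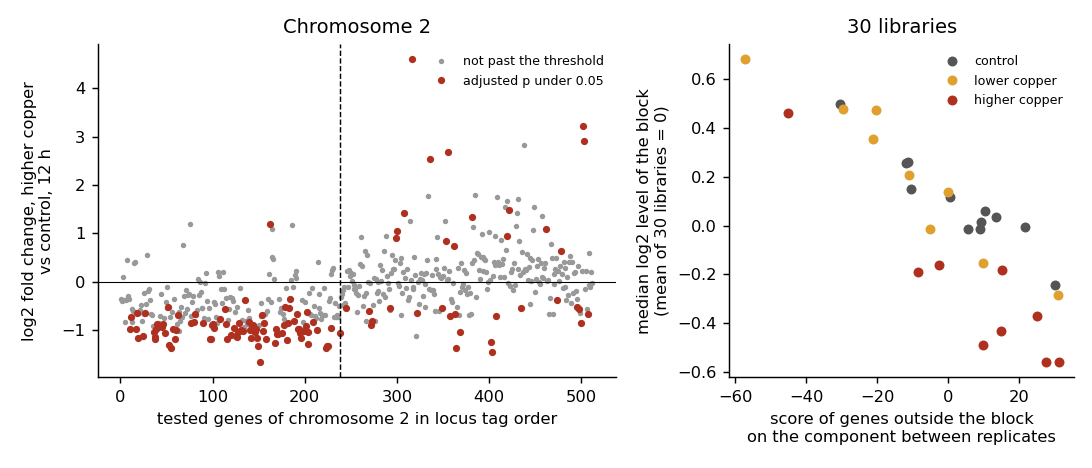
Left, log2 fold change of higher copper against control at 12 h (vertical axis) for the 512 tested genes of chromosome 2 in the order of their locus tags (horizontal axis), with a dashed line after OT_ostta02g02710. Right, median log2 level of the 293 genes of that part and of chromosome 19 (vertical axis) against the score of the component between replicates, computed from the other genes (horizontal axis), for 30 libraries; the part left of the line had a median of −0.67 and the rest of chromosome 2 of 0.10.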

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

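Which gene to name here, and its values by group, were chosen after the counts were seen, whereas the tests of a change between times and of other splits of the samples were set before. The effect of higher copper differed between 4 and 1 h, by edgeR, for 1 gene, OT_ostta03g02950, with a difference of 2.54 ± 0.43 (log2, SE; adjusted p = 0.027). The files give no function for it. It stood at 19.7 ± 7.57 CPM under higher copper at 4 h against 2.81 ± 0.195 CPM in the control (SD, n = 3), and at 5.97 ± 0.873 against 4.97 ± 0.588 CPM at 1 h. Its log2 change was 0.25 at 1 h, 2.79 at 4 h (adjusted p = 1.1e-05) and 1.84 at 12 h (adjusted p = 0.00059), and 1.89 under lower copper at 4 h (adjusted p = 0.022). The call was lost with the labels of the doubted controls exchanged, with both left out and with only the groups compared (243 genes at an unadjusted p under 0.05 with all libraries; DESeq2 called 1 gene with the labels as deposited). It was also lost without control 1 h replicates 2 or 3, any control at 4 h, higher copper 1 h replicates 2 or 3, or higher copper 4 h replicate 1.

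Splits of the libraries give no reference without a change for these differences. A split that keeps or mirrors the real groups at 1 of the times carries the copper effect itself into the difference, and where the real count is 0 every split gives as many. For the change from 1 to 4 h under higher copper, 12 of 100 splits gave at least 1 gene. The highest other value, 779, came from the 22 splits that keep or mirror the real groups at a time, and the 77 splits mixed at both times gave 0 (edgeR; 243 at an unadjusted p under 0.05 in the real split; DESeq2 called 1). Whether chance gives the call of OT_ostta03g02950 is therefore left open.

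For the change from 4 to 12 h under higher copper edgeR gave 0 genes (557 at an unadjusted p under 0.05; DESeq2 called 14), and the highest other value of 100 splits was 535, with 2 among those mixed at both times. Under lower copper both changes gave 0 genes by edgeR (95 and 292 at an unadjusted p under 0.05; DESeq2 called 0), with highest values of 25 and 80, and of 0 and 2 among mixed splits. Modules gave 0 for each of the 4 changes by edgeR (6, 4, 4 and 15 at an unadjusted p under 0.05; DESeq2 called 0, 0, 0 and 1), with highest values of 2, 49, 42 and 25. The 49 came from a split mixed at both times.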

How the results depend on the processing

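Exchanging the labels of the doubted controls, leaving both out, adding the component between replicates as a covariate, and every alternative for modules were chosen after the data were seen. No fold change of a gene named by the rule or of a called module reversed its direction under any alternative. Other fold changes in the text were not all checked in this way. The balance of rises and falls turned in some alternatives. With the component as a covariate 44.3% of the lower copper calls at 4 h rose, against 72.2%. With only the groups compared 53.8% of the higher copper calls at 12 h rose, against 41.1%. For higher against lower copper at 12 h 51.1% rose with the covariate and 51.4% without a filter, against 46.3%. The 661 and 852 genes called under higher copper at 4 and 12 h stayed within 1.5 times under DESeq2 size factors, the DESeq2 Wald test, no filter, the replicate block, exchanged labels and both doubted controls left out. DESeq2 shared 655 and 844 of these genes. For each value below that moved by over 1.5 times the cause was not tested.

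With the DESeq2 Wald test, lower copper gave 102 genes at 4 h and 10 at 12 h, higher copper 213 at 1 h, higher against lower copper 129 and 278 at 4 and 12 h, the control 108, 144 and 585 at 1, 4 and 12 h, and the change from 4 to 12 h under higher copper 14. Its modules numbered 1 and 4 for lower copper at 1 and 12 h, 13 and 14 for higher against lower copper at 4 and 12 h, 5 and 31 for the control at 1 and 12 h, and 1 for the change from 4 to 12 h. With DESeq2 size factors, higher against lower copper gave 7 genes at 4 h, the control 9 at 1 h, and the change from 4 to 12 h 1 module. Without a filter these genes numbered 7 and 3. At an adjusted p under 0.01 the doses shared 0 genes at 4 h. With DESeq2 fold changes Spearman's rho with the deposited tables ran from 0.921 to 0.977 over the 9 comparisons, against 0.948 to 0.994 with edgeR. It was 0.963 for lower copper at 4 h, 0.977 for higher copper at 12 h and 0.969 for higher against lower copper at 4 h.

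The replicate numbers did not pair the libraries throughout. The mean correlation of deviations from group means was 0.0648 for libraries of the same number and −0.0326 for different numbers. It was over 0.1 for all 3 numbers in 4 of 45 pairs of groups, and 16 of 30 libraries lay closest to their own number. Pairing is thus neither shown nor excluded. A block for the numbers gave 37 genes for lower copper at 4 h, and 24 and 206 for higher against lower copper at 4 and 12 h. It gave 9, 38 and 450 for the control at 1, 4 and 12 h, and 35 shared by the doses at 4 h. Its modules numbered 4 and 12 for higher against lower copper, 8 for the control at 1 h and 1 for the change from 4 to 12 h. With only the groups compared, lower copper gave 204 genes at 4 h, higher copper 0 at 1 h and 1028 at 4 h, higher against lower copper 0 at 4 and 12 h, the control 54, 149 and 619, and the change from 1 to 4 h 0. Modules then numbered 0 for lower copper at 12 h, 0 for higher copper at 1 h, 0 for higher against lower copper at 4 and 12 h, and 4 and 12 for the control at 1 and 12 h.

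With the labels of the doubted controls exchanged, lower copper gave 0 genes at 4 h, higher copper 205 at 1 h, the control 29 at 1 h and 34 at 4 h, the changes under higher copper 0 and 2, and the doses shared 0 at 4 h. Modules numbered 0 for lower copper at 12 h, 1 for higher copper at 1 h, 0 for higher against lower copper at 4 h, and 0 and 6 for the control at 1 and 4 h. With both left out, the genes numbered 0 for lower copper at 4 h, 0 and 6 for the control at 1 and 4 h, 0 and 3 for the changes, and 0 shared at 4 h. Modules numbered 6 for higher copper at 1 h, 0 and 1 for higher against lower copper at 4 and 12 h, and 1 for the control at 4 h. With the component as a covariate, lower copper gave 79 genes at 4 h and 1 at 12 h, higher copper 694 at 1 h and 1584 at 4 h, higher against lower copper 202 and 362, the control 133, 312 and 488, and the change from 4 to 12 h 5. Modules numbered 2 and 5 for lower copper at 4 and 12 h, 39 and 58 for higher copper at 1 and 4 h, 10 and 15 for higher against lower copper, 9, 24 and 42 for the control, and 1 and 4 for the changes.

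Leaving out 1 library at a time gave 0 to 64 genes for lower copper at 4 h and 0 at 1 and 12 h, 0 to 155, 380 to 783 and 297 to 1087 for higher copper at 1, 4 and 12 h, 0 to 63 and 61 to 661 for higher against lower copper at 4 and 12 h, 0 to 14, 0 to 44 and 42 to 512 for the control, and 0 to 1 and 0 to 4 for the changes under higher copper. Modules ranged from 0 to 5 for lower copper at 12 h, 0 to 16, 14 to 27 and 8 to 44 for higher copper, 0 to 7 and 1 to 15 for higher against lower copper, 0 to 5, 1 to 14 and 7 to 28 for the control, and 0 to 1 for the change from 4 to 12 h.

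Of 33 named gene values and 109 module values, 11 and 50 were no longer called with only the groups compared, 8 and 35 with both doubted controls left out, 6 and 23 with their labels exchanged, 3 and 5 with DESeq2 size factors, and 1 and 3 with the component as a covariate. The 7 gene values for which DESeq2 gave no adjusted p have no value under that test. Set tests with camera were not run.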

Other observations

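The tests of whether a pair of control libraries is exchanged and whether depth explains it, and those of the block on chromosomes 2 and 19, were chosen after the results were seen, as was the choice of the modules named next.

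Outside the lists, the module of the DNA-PK complex (M00297), which joins broken DNA ends, rose under higher copper at 12 h by 0.72 ± 0.20 (log2, SE), to 1760 ± 293 from 1070 ± 179 CPM (n = 3; edgeR adjusted p = 0.016). The H/ACA ribonucleoprotein (M00425), which guides pseudouridylation of RNA, fell by 0.80 ± 0.23, from 5610 ± 792 to 3230 ± 785 CPM (adjusted p = 0.018). Elongation of fatty acids in the endoplasmic reticulum (M00415) fell by 0.72 ± 0.18 (adjusted p = 0.011), and sphingosine degradation (M00100) fell by 0.95 ± 0.26, from 1980 ± 320 to 1020 ± 237 CPM (adjusted p = 0.015). Without higher copper 12 h replicate 3 none of the 4 was called by edgeR. The H/ACA and sphingosine modules were also lost without higher copper 12 h replicate 2 or control 12 h replicate 3, and DNA-PK without control 12 h replicate 2.

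Control replicate 3 at 1 h and at 4 h appear exchanged in 1 of the 2 tables. Of 30 module columns, 2 were nearest to the gene column of another library, which is consistent with exchanged labels in 1 table. A difference in depth is argued against, since the smaller ratio of distance to own over distance to partner was 2.4 with both tables scaled to totals. On an axis from the other 1 h controls (0) to the other 4 h controls (1), the gene column labelled 1 h lay at 0.904 and that labelled 4 h at 0.403, which suggests that the gene table has the wrong labels. No biological explanation was tested for a pair of labels.

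Genes of chromosome 19 and of the first part of chromosome 2, which differ in base composition from the rest of this genome, fell as a block under higher copper at 12 h, by a median of −0.66 ± 0.24 (SE, n = 3). The block's level followed the component between replicates within groups over 30 libraries (Pearson's r −0.944, Spearman's rho −0.935, permutation p = 1e-05 for both, the smallest that 100000 permutations give; r −0.924 without the 2 farthest libraries). The edge on chromosome 2 was placed by the loadings on the main component within groups, so this correlation was largely fixed by that choice. Its permutation p does not account for the choice. Expression level is argued against as the whole cause, since the difference was −0.596 ± 0.19 against matched genes. With the component held fixed by a linear slope the difference was −0.358 ± 0.083. The component's score, computed from the other genes, thus does not account for all of the difference. A part of the component that this score misses stays open. With total counts held fixed the difference was −0.618 ± 0.29, moved by less than its standard error, so this does not decide on depth. Over 1, 4 and 12 h the exact stratified permutation p of higher copper (two-sided, component held fixed) was 0.00025, the smallest that 8000 arrangements give, but it includes the 12 h difference that drew attention to these genes. With the component held fixed the block also lay at −0.278 at 1 h and −0.338 at 4 h. The 1 h difference came mainly from chromosome 2. Without the covariate, the median log2 fold change at 1 h was −0.277 for its part of the block and −0.0429 for chromosome 19. At 4 h these medians were −0.336 and −0.164. Over 1 and 4 h the exact permutation p of the block with the component held fixed was 0.005, the smallest that 400 arrangements give. Unadjusted it was 0.1 (−0.296 and −0.325), and this test was chosen after the block's differences were seen. With the 12 h difference included, the unadjusted exact stratified permutation p was 0.0058. The block was cut by its loadings on the component, so holding that component fixed removes most of the block's spread between replicates through that choice. The p-values and standard errors with the component held fixed do not account for this. Under lower copper the differences were −0.083, −0.0763 and −0.0387 at 1, 4 and 12 h with the component held fixed (exact stratified permutation p = 0.11). Unadjusted they were 0.0167, 0.211 and −0.0517 (exact stratified permutation p = 0.65), so the sign at 1 and 4 h depended on the adjustment. Higher copper may be a cause. A part of the component that its score misses, depth, base composition bias and copy number stay open beside it.

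Cell cycle, checkpoint and replication modules (M00692, M00691, M00288, M00263) rose and GINS (M00286) fell under higher copper at 12 h. These 5 were chosen among called modules. APC/C (M00389), which also rose, is not among them and was lost without higher copper 12 h replicate 3 or control 12 h replicates 1 or 3, and 5 of the 10 modules of the list did not pass. With the component of the module counts as a covariate 5 of the 5 were called. The covariate also removes spread within groups by construction, which favours calls, so the number called does not decide. The log2 fold changes were then 0.91 (G1/S), 1.34 (checkpoints), 0.40 (RPA), 0.68 (polymerase epsilon) and −0.52 ± 0.11 (GINS, before −0.75 ± 0.19). By these sizes that component, as its score measures it, is argued against as the whole cause. The component of the gene counts was not held fixed in this fit. With every library thinned to the lowest total 5 were called as well, but thinning moved each fold by less than its standard error (0.91 ± 0.12 both before and after for G1/S), so a difference in depth stays open. So does a single library, since 2 of the 5 were called without higher copper 12 h replicate 3, 4 without control 12 h replicate 3, and 5 without each of the other 4 libraries compared. G1/S and the checkpoints were called without each of the 6. Without higher copper 12 h replicate 3 the other 3 lay at 0.28 ± 0.08 (RPA, before 0.39 ± 0.084), 0.47 ± 0.16 (polymerase epsilon, before 0.59 ± 0.15) and −0.70 ± 0.22 (GINS, before −0.75 ± 0.19), and without control 12 h replicate 3 GINS lay at −0.63 ± 0.19. Their direction and most of their size were thus kept, and a part due to 1 library and the lower power of 2 libraries cannot be told apart for these 3. A shift of the cell cycle under higher copper stays open beside these.

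A hypothesis set before its test was that higher copper holds back the time course seen in the lower copper libraries. On an axis of 112 genes the higher copper libraries lay at −0.485 from the control at 4 h and −0.0655 at 12 h (exact stratified permutation p = 0.015, two-sided, 400 arrangements; p = 0.02 with the component held fixed). Nearly all of the difference was at 4 h, so the result suggests a delay no more than a response at 4 h. As noticed afterwards, the axis also holds any lower copper response present at 4 h and gone at 12 h, and it does not separate these.

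A further hypothesis was that lower copper moves the 12 h genes of higher copper earlier and in the same direction. The signed score of these 852 genes was 0.0925 above the control at 1 h and 0.148 at 4 h under lower copper (exact stratified permutation p = 0.04, two-sided, 400 arrangements), and p = 0.015 for the 746 genes outside the block. A weaker common response is a possible reading. The mean score under higher copper was 0.467 (exact stratified permutation p = 0.005, the smallest that 400 arrangements give). Both scores were set against the same controls at 1 and 4 h, which alone can move them alike. Their likeness at these times is therefore no separate evidence.

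For each comparison of 3 against 3 libraries, 10 splits exist, so a share under 0.05 cannot be reached. The real split and the highest other gave 18 and 0 genes for lower copper at 4 h, 110 and 0, 661 and 0, and 852 and 141 for higher copper at 1, 4 and 12 h, 12 and 0 and 121 and 0 for higher against lower copper at 4 and 12 h, and 1 and 0, 17 and 0, and 294 and 2 for the control at 1, 4 and 12 h. For lower copper at 1 and 12 h edgeR gave 0 genes in all 10 splits (266 and 339 at an unadjusted p under 0.05 in the real split; DESeq2 called 0 and 10), and for higher against lower copper at 1 h 0, with 1 in the highest other (325; DESeq2 called 0). For modules these values were 12 and 0, 20 and 0, and 39 and 6 for higher copper, 2 and 0 at 4 and at 12 h for higher against lower copper, 1 and 0, 12 and 0, and 20 and 0 for the control, and 1 and 10 for lower copper at 12 h, where 5 of the 10 splits gave as many. Modules numbered 0 by edgeR in all splits for lower copper at 1 and 4 h (20 and 16 at an unadjusted p under 0.05; DESeq2 called 1 and 0), and 0 against 14 in the highest other for higher against lower copper at 1 h (9; DESeq2 called 0).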
